A study of Arabidopsis thaliana with 9 samples.

How the data were processed

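Transcript levels were measured in whole rosettes of Arabidopsis thaliana harvested 15 days after sowing. Per the labels, the plants were Col-0 (called Col here), C24 and their F1 hybrid, written C24 x Col in the series description, with 3 biological replicates of each, so that 9 samples were hybridised to 9 one-colour Affymetrix arrays. Per the labels' protocols, seeds were sown on agar plates of Murashige and Skoog medium, total RNA was isolated from the rosette leaves with a Qiagen RNeasy kit, and biotin-labelled cRNA was prepared by the array maker's standard procedure. The labels describe the replicates as biological; how many plants went into each sample, the time of day at harvest, the days on which arrays were processed and which line was the seed parent are not given in the sources used here. No batch could therefore be tested, beyond the replicate number as a block.

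The values are intensity values as deposited: linear signals, 1 per probe set and array, made with MAS5 per the submitters' processing notes, whose version, settings and scaling target are not given in the sources used here. MAS5 combines the probes of a probe set into 1 signal and scales each array by 1 factor. The mean signal after trimming 2% at either end lay between 500.049 and 500.054 on the 9 arrays, so the arrays had been scaled to a common mean before deposit. Median signals per array ran from 158.5 to 174.4. Because of this scaling a difference is relative to the rest of the array, and a change of the whole RNA content would not be seen. Arrays give no read depth; their number limits the precision.

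The table held 22810 probe sets, of which 64 were the array maker's controls and were set aside. The platform annotation gave 1 gene for 13513 probe sets, several for 503 and none for 8730; a probe set with several genes was not named. Of the probe sets with 1 gene, 13436 were matched to a RefSeq gene table (assembly TAIR10.1), which was used only for names, for gene order and for which genes are chloroplast-encoded; no coordinates are given because the sources used here name no build for the probes. A probe set without a name here is not one without a gene, and many well-known genes are therefore not reported. Of the 8 genes to be reported in any case (FLC, CCA1, LHY, TOC1, GI, PR1, PIF4 and FRI), the annotation named GI. Names are those of the annotation: CHI here is the chitinase gene AT2G43570, not chalcone isomerase.

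Signals were log2-transformed with no further scaling. Probe sets whose mean log2 signal over the 9 arrays lay below the 40th percentile (6.49, a signal of 89.9) were left out, which left 13648 to be tested, 7354 of them with 1 gene (7314 genes). A mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that the 3 groups shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05 on the adjusted p; every adjusted p for a probe set comes from limma and is two-sided unless stated. The mid-parent level was the mean of both parents on the linear scale, taken to log2, with a standard error from the delta method and limma's moderated spread. F1 was called above (or below) both parents when both differences had that sign and the larger of their 2 p-values passed the threshold after adjustment. Those p-values, F1 against each parent, were two-sided. The position of F1 between the parents was computed on linear signals, where 0 is the Col mean, 1 is the C24 mean and 0.5 is additive, as the median over probe sets whose parents differed at least 2-fold and past the threshold. Some probe sets named for 1 gene carry the suffix _s_at or _x_at and can also bind transcripts of related genes; those of PDF1.2b and AT5G34920 are of this kind. Where 1 gene had several probe sets tested (39 genes) the list tests used the brightest; the parental log2 differences of such probe sets spanned a median of 0.30, and 0 of the 39 had calls in opposite directions.

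The design, the alternatives, 17 gene lists of pathways (433 genes), 5 lists of cell or organ markers and 1 list of reference transcripts, and the rule for naming genes were fixed before the data were examined. The annotation named 62 of the 433 genes and 57 were tested, which left 9 lists with at least 3 members. The pathway lists covered photosystems and electron transport, the Calvin-Benson cycle, chlorophyll biosynthesis, flavonoids and anthocyanins, glucosinolates, starch metabolism, auxin response and PIF, cold and abscisic acid, salicylic acid and defence, jasmonate, heat and chaperones, senescence and sugar starvation, the circadian clock, flowering time, the cell cycle and growth regulators, DNA methylation and silencing, and cytosolic ribosomal proteins. Because so few were named, 14 further lists were added after seeing which genes the annotation names and before any test was run; 13 had at least 3 members tested. These were gene families defined by their symbols, plus chloroplast-encoded and mitochondrion-encoded genes. Lists were tested with limma's camera against all other genes at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, which asks only whether the list's own genes move; the p-values were adjusted over the lists of each kind and comparison. For the mid-parent the list test used the mean of the parents' log2 values.

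The genes named were, for each comparison, the 8 highest and 8 lowest log2 differences among probe sets of 1 gene past the threshold whose groups did not overlap (for the mid-parent, with every F1 array on 1 side), up to 4 members of each list with the smallest p-values, and for F1 above or below both parents the 8 smallest p-values in either direction. The steps were tested on simulated data for 13648 probe sets with 200 changed (100 for levels beyond both parents), in 5 runs. The comparison of C24 with Col recovered 77.8% of 2-fold and 98.2% of 4-fold changes with 4.62% false calls. The mid-parent comparison recovered 86.2% and 98.8% with 4.64% false calls, and called 0% of the additive probe sets. Levels above both parents were recovered in 66.0% and 96.4% of cases with 0.43% false calls. Levels below both were recovered in 67.6% and 95.2%, where false calls were not counted. Noise was drawn independently for each probe set. Deviations shared between genes were thus not simulated, and the rates of false calls hold for that setting only. An additive F1 gave a position of 0.501.

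The alternatives were quantile normalization, median centring, no filter or a 60th-percentile filter on low signals, a pseudocount of 25.3 (the 20th percentile of all signals), no intensity trend, probe sets without the suffixes _s_at and _x_at, the replicate number as a block, only the 6 arrays of the 2 groups compared, other thresholds, the log2 scale for the mid-parent and the position, and each array left out in turn. Signals below 1 made up 0.358% of the values (732), with 0 among the probe sets tested. Array controls with probe sets at the 3' end, middle and 5' end of a transcript gave 38 ratios; F1 was set against the 6 parental arrays by an exact permutation test over 84 splits. Figures were drawn with matplotlib 3.10.9.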

Results

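Whole rosettes of 2 Arabidopsis accessions, Col and C24, and of their F1 hybrid were profiled 15 days after sowing, with 3 biological replicates in each of the 3 groups. Each of the 9 arrays gave MAS5 signals for 22810 probe sets, of which 13648 were tested. Across probe sets, which are not independent replicates, log2 signals correlated at 0.977 to 0.983 between replicates, at 0.895 to 0.902 between C24 and Col, at 0.947 to 0.961 between Col and F1 and at 0.939 to 0.952 between C24 and F1. The first principal component held 60.4% of the variance and put the F1 arrays (-6.78 to 3.35) between Col (-42.0 to -39.4) and C24 (41.8 to 44.2). The second held 12.8% and set F1 (-22.8 to -21.4) apart from both parents (9.21 to 14.1). Signals are given as mean ± SD with n = 3 arrays, differences on the log2 scale.

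The comparison of the inbred parents asked which transcripts differed between C24 and Col rosettes. PDF1.2b (AT2G26020) and PDF1.2 (AT5G44420), which encode plant defensins, stood at 9045 ± 2046 and 3564 ± 763 in C24 against 7.67 ± 3.45 and 79.0 ± 15.2 in Col, log2 differences of 10.27 (SE 0.74, adjusted p = 5.55e-08) and 5.49 (SE 0.77, adjusted p = 5.78e-05). The chitinase gene CHI (AT2G43570) stood at 2398 ± 322 in C24 and 35.4 ± 23.7 in Col, a log2 difference of 6.44 (adjusted p = 6.79e-07). In the other direction NAI2 (AT3G15950), a component of endoplasmic reticulum bodies, stood at 732 ± 139 in Col and 4.48 ± 2.88 in C24 (log2 difference -7.60, SE 0.43, adjusted p = 4.66e-09), and ECS1 (AT1G31580), a cell-wall protein gene, at 21099 ± 1322 and 147 ± 20.7 (log2 difference -7.17, SE 0.11, adjusted p = 6.63e-16).

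The other genes with the highest ratio in C24 were AT3G48640, AT5G34920, AT4G29200, AT5G55450 and AT4G19430, with log2 differences of 6.65, 6.42, 6.37, 6.13 and 5.90. AT5G55450, of the lipid-transfer protein family, reached 8047 ± 467 in C24 against 122 ± 46.3 in Col. The other genes with the lowest ratio were AT1G23960, AT5G45500, AT4G16880, QQS, 2A6 and AT4G19500, with log2 differences of -7.23, -6.11, -5.99, -5.18, -5.12 and -5.08. QQS (AT3G30720), an orphan gene tied to starch content, stood at 534 ± 218 in Col and 18.6 ± 12.7 in C24. Where the lower group lay far under the filter signal of 89.9, as for PDF1.2b and NAI2, the size of the fold rests on signals near the bottom of the scale. Leaving out 1 array moved some of them by over 1.5-fold: without Col replicate 1 AT5G34920 was 5.82 and AT4G19430 6.63, without Col replicate 2 AT3G48640 was 5.83, CHI 5.63 and AT5G34920 7.32, and without Col replicate 3 AT4G19430 was 4.74. Without C24 replicate 1 NAI2 was -6.96, AT4G16880 -6.76 and AT4G19500 -5.74, without C24 replicate 2 QQS was -4.28 and AT4G19500 -4.43, and without C24 replicate 3 AT4G16880 was -5.28. GI (AT1G22770), a circadian clock gene, was higher in C24 (886 ± 52.6 against 558 ± 33.9, log2 difference 0.67, adjusted p = 0.000798).

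**Figure D1:**
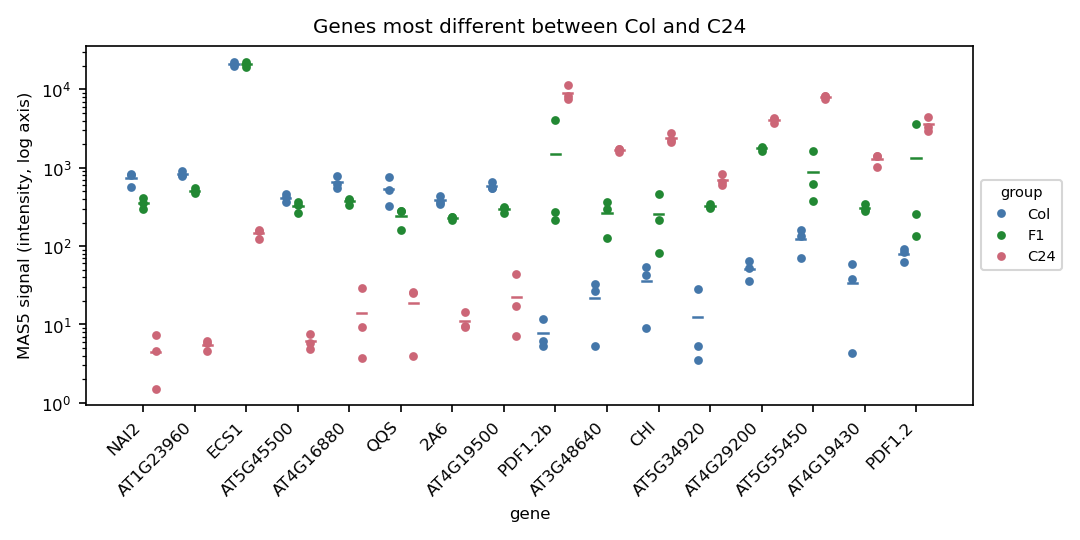
Signals of the 16 genes with the highest and lowest C24 to Col ratio, on a log axis of MAS5 signal. Each point is 1 array, the dash is the mean of 3 arrays, and colours mark Col (blue), F1 (green) and C24 (red). F1 of ECS1 (20823 ± 1556) lay at the level of Col, and F1 of NAI2 (354 ± 54.4) stood between the parents.

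In all, 4220 probe sets (30.9%) differed between the parents in limma, 2139 higher and 2081 lower in C24 (1845 and 2158 after quantile normalization, 1751 and 2462 after median centring), and 1076 of them at least 2-fold (569 higher, 507 lower). The groups did not overlap in 6136 probe sets (45%), where chance gives 10%. An exact test of 3 against 3 arrays could not go below p = 0.1 for a single gene, so calls rest on limma's shared spread.

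Of the lists fixed beforehand, 2 of 9 passed the camera test. Among flavonoid and anthocyanin genes, 3 of 4 fell in C24 (4 of 4 when adjusted over the list alone), with a median of -1.46 (adjusted p = 0.00245, and adjusted p = 0.309 with an estimated correlation). They were DFR (dihydroflavonol reductase, 620 ± 55.8 in Col and 175 ± 35.4 in C24, -1.84), and the anthocyanin glycosyltransferase genes UGT79B1 (-2.08) and UGT75C1 (-1.08); the fourth, UGT78D2, differed by -0.31. Among cold and abscisic acid genes, 3 of 5 rose in C24 (4 of 5 when adjusted over the list alone), with a median of 0.66 (adjusted p = 0.0378, and adjusted p = 0.309 with an estimated correlation). They were the cold-regulated genes COR15A (0.64) and COR15B (1.29) and the zinc-finger repressor gene STZ (2.47), while COR47 differed by 0.66 (adjusted p = 0.0619) and LTI30 by -0.10. The cold list's call was lost without C24 replicate 2 (adjusted p = 0.0943), without F1 replicate 1 (adjusted p = 0.0582) and with the 60th-percentile filter (adjusted p = 0.105).

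With the estimated correlation 0 of the 9 lists passed, 1 had an unadjusted p under 0.05, and fry gave 4 such lists. Of 8 genes of photosystems and electron transport 4 fell, among them LHCB4.2, an antenna protein gene (30716 ± 1643 in Col, 21505 ± 892 in C24, -0.51), and the list did not pass (adjusted p = 0.0717, with 0.0478 after median centring, where adjusted p = 0.626 with an estimated correlation, and 0.908 after quantile normalization). Of 4 Calvin-Benson genes 2 fell, PRK (-0.23) and SBPASE (-0.20), with adjusted p = 0.535 for the list. In chlorophyll biosynthesis CHLM fell (-0.62) and PORB rose (0.47) of 7. IAA29 rose (1.51) of 6 genes of auxin response and PIF, BCAT4 rose (0.68) of 4 glucosinolate genes, and 0 of 5 cytosolic ribosomal protein genes changed. Of 3 flowering-time genes AGL24 fell (-0.72) and SNZ rose (0.71); these 5 lists each had an adjusted p of 0.991.

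Lists with under 3 genes tested had no list test. Both genes of salicylic acid and defence rose, SAG101 by 1.26 and GRX480 by 2.07. PDF1.2 was the jasmonate gene tested and GI the clock gene. ROF2, a heat-shock binding protein gene, fell (-1.40), as did APL3, a starch synthesis gene and 1 of 2 tested (-0.82), and MCM7, a DNA replication gene and 1 of 2 of the cell cycle list (-0.70). The senescence gene SAG29 stood at 256 ± 67.6 in Col and 157 ± 125 in C24 (adjusted p = 0.116). The brighter probe set of the DNA demethylase gene DME differed by 0.04 (adjusted p = 0.887) and its other probe set by 0.68 (adjusted p = 0.00594). Of the organ markers, the root gene PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies, stood at 2726 ± 219 in Col and 92.0 ± 40.5 in C24 (-4.98, adjusted p = 2.96e-10), and the stomatal gene FAMA differed by -0.22 without passing. The lists for seed storage, shoot meristem and vasculature had 0 genes tested. Of 6 reference transcripts 2 fell, by -0.53 for AP2M and -0.39 for the other.

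F1 against Col asked how the hybrid differed from that parent. PDF1.2b (6.43), AT5G34920 (5.31), AT4G29200 (5.16) and AT3G60920 (4.62), low in Col and higher in C24, were higher in F1 than in Col. STZ rose from 53.8 ± 17.7 in Col to 885 ± 171 in F1 (4.07, SE 0.21, adjusted p = 6.34e-09), and AT4G27280, which encodes a calcium-binding protein, from 357 ± 56.9 to 5233 ± 320 (3.88, adjusted p = 2.22e-10); AT4G19430 (3.86) and AT3G48640 (3.83) completed the highest. Leaving out 1 array moved the ratio of 5 of these by over 1.5-fold: PDF1.2b was 7.19, 5.07 and 7.02 without F1 replicates 1, 2 and 3, AT5G34920 4.72 and 6.22 without Col replicates 1 and 2, AT4G19430 4.59 and 2.70 without Col replicates 1 and 3, AT3G48640 3.01 without Col replicate 2 and AT3G60920 4.03 without Col replicate 3. The lowest were the chloroplast-encoded petG (-1.80, adjusted p = 1.61e-06), AT3G44970 (-1.77, adjusted p = 0.0410), AT4G21870 (-1.74), AT2G36885 (-1.50), the chloroplast-encoded rpl20 and ndhE (-1.47 and -1.33), ASPGB1 (-1.47) and AT1G29270 (-1.32). AT4G21870, a small heat-shock protein gene, stood at 1101 ± 27.9 in Col, 271 ± 20.8 in C24 and 331 ± 26.2 in F1.

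In this comparison 1563 probe sets (11.5%) passed, 869 higher and 694 lower in F1, and 331 did so at least 2-fold (276 higher, 55 lower); without Col replicate 2 the count was 1021. The groups did not overlap in 3961 probe sets (29.0%, against 10% by chance). Cold and abscisic acid genes passed as a list, with 3 of 5 higher (COR15A 0.74, COR15B 1.22 and STZ) and 4 when adjusted over the list alone (median 0.74, adjusted p = 0.00132, and adjusted p = 0.192 with an estimated correlation). Flavonoid and anthocyanin genes passed as well, with 3 of 4 lower, DFR and UGT78D2 among them (-0.63 and -0.55), and 4 when adjusted over the list alone (median -0.59, adjusted p = 0.00132, and adjusted p = 0.222 with an estimated correlation). GI was 810 ± 125 in F1 (0.53, adjusted p = 0.0127); its call was lost without F1 replicate 2 or 3 (adjusted p = 0.0593 and 0.0566). The call of AT3G44970 was lost without any of the Col or F1 arrays (adjusted p = 0.0858 to 0.118), with no filter (0.0815) and without an intensity trend (0.102).

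F1 against C24 asked the same of the other parent. ECS1 (7.15), NAI2 (6.56), AT1G23960 (6.53), AT5G45500 (5.73), AT4G16880 (5.21), AT3G22240 (4.66), PYK10 (4.53) and 2A6 (4.37) were the highest in F1. PYK10 stood at 1985 ± 143 in F1 (adjusted p = 3.37e-09). The lowest were AT5G44570 (-4.25, adjusted p = 9.64e-09), PDF1.2b (-3.84), CHI (-3.56), AT5G55450 (-3.47), petG (-3.04), CML41 (-2.89), AT3G48640 (-2.82) and AT2G44380 (-2.78). Leaving out 1 array moved the ratio of 4 of these by over 1.5-fold: PDF1.2b was -3.08, -5.20 and -3.25 without F1 replicates 1, 2 and 3, CHI -4.17 and -2.92 without F1 replicates 2 and 3, NAI2 5.92 without C24 replicate 1, and AT4G16880 5.97 and 4.49 without C24 replicates 1 and 3. The calmodulin-like gene CML41 (AT3G50770) stood at 770 ± 221 in C24, 88.9 ± 26.0 in Col and 103 ± 20.9 in F1.

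Here 1951 probe sets (14.3%) passed, 1030 higher and 921 lower in F1 (1115 and 866 after quantile normalization, 1274 and 762 after median centring), and 450 did so at least 2-fold (257 higher, 193 lower). The groups did not overlap in 4487 (32.9%, against 10% by chance). Of the 9 lists fixed beforehand camera passed 0, with the preset and with the estimated correlation; fry gave 3 and the estimated correlation 0 at an unadjusted p under 0.05. Of the flavonoid and anthocyanin genes 2 of 4 were higher in F1, DFR among them (1.21), with adjusted p = 0.198 for the list. GI differed by -0.14 (adjusted p = 0.518).

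Where the parents differed at least 2-fold (1076 probe sets), the median position of F1 was 0.432 ± 0.044 (SD, n = 3 F1 arrays), with all 3 F1 arrays on the Col side of the additive 0.5 (0.413, 0.482 and 0.3997), and 0.434 on the log2 scale. With 3 arrays this distance from 0.5 was not tested. On linear signals it was 0.361 ± 0.072 for the 569 probe sets higher in C24 and 0.486 ± 0.023 for the 507 higher in Col. On the log2 scale, where an additive F1 lies nearer the higher parent and not at 0.5, that order turned, to 0.521 and 0.346. Where the parents differed at least 4-fold (297 probe sets) it was 0.381 ± 0.056.

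F1 against the mid-parent asked which transcripts were not at the mean of both parents. AT3G22240 stood at 15270 ± 7165 in F1 against 1078 ± 392 in Col and 587 ± 215 in C24 (4.17, SE 0.27, adjusted p = 5.70e-07), AT4G27280 was at 2.67 (adjusted p = 6.78e-08), STZ at 2.36 (SE 0.20, adjusted p = 4.62e-06), and ORA47 (AT1G74930), a jasmonate-responsive AP2/ERF transcription factor gene, at 2.16, with 659 ± 83.7 in F1, 125 ± 29.4 in Col and 171 ± 15.7 in C24. Below the mid-parent, PDF1.2b, CHI and AT5G55450 were at -2.85 (adjusted p = 0.0499), -2.58 (adjusted p = 0.0221) and -2.49 (adjusted p = 0.00106), with F1 signals of 1519 ± 2209, 254 ± 196 and 873 ± 658. AT5G44570 was lowest (-3.31, adjusted p = 9.90e-07), with 56.5 ± 7.63 in F1, 47.3 ± 9.25 in Col and 1085 ± 227 in C24.

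The other highest genes were AT2G20670 (2.16), AT3G07350 (1.83), AT1G32920 (1.80) and AR781 (1.77). The other lowest were petG (-2.55), CML41 (-2.05, adjusted p = 0.000134), AT2G44380 (-1.91) and AT1G10340 (-1.74, adjusted p = 0.0168). ECS1 was above the mid-parent (0.97, adjusted p = 4.38e-05), its F1 signal being close to that of Col. GI was not set apart (0.16, adjusted p = 0.518). F1 replicate 2 stood above the other F1 arrays in PDF1.2b (4070 against 215 and 272), CHI (468 against 212 and 82.5), AT5G55450 (1620 against 619 and 381) and PDF1.2 (3617 against 135 and 255), and without it PDF1.2b, CHI and AT5G55450 were at -4.20, -3.19 and -3.07, each past the threshold. The calls of PDF1.2b, CHI and AT1G10340 were lost in 11, 5 and 3 of the alternatives. Without F1 replicate 1 PDF1.2b was at -2.08 and without F1 replicate 3 at -2.25, where CHI was at -1.94. Without F1 replicate 1 the adjusted p was 0.189 for PDF1.2b, 0.0671 for CHI and 0.0804 for AT1G10340, and without F1 replicate 3 it was 0.189, 0.104 and 0.0895. PDF1.2b also lost its call without each Col or C24 array (adjusted p = 0.0611 to 0.137), and CHI without C24 replicate 1 or 3 (0.0545 and 0.0669).

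In limma 450 probe sets (3.3%) differed from the mid-parent, 229 higher and 221 lower in F1, and 103 at least 2-fold (55 higher, 48 lower). With the mean of the parents' logs the count was 508 (349 higher, 159 lower). Without F1 replicate 3 it was 284, and without an intensity trend 264.

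Of the 9 lists fixed beforehand 1 passed against the mid-parent. Of 5 cold and abscisic acid genes STZ was called, and 3 were higher when adjusted over the list alone. The median was 0.39 on the linear mid-parent and 0.42 on the mean of logs that the test used (adjusted p = 0.00513, and adjusted p = 0.248 with an estimated correlation). With that correlation 0 lists passed and 1 had an unadjusted p under 0.05, as did 1 with fry. Single genes of other lists were called: UGT78D2 was lower (-0.40), LHCB4.3, an antenna protein gene, was lower (-0.33), and HAT2, an auxin-induced homeobox gene, was higher (0.56, with 886 ± 59.2 in F1, 668 ± 59.3 in Col and 539 ± 26.1 in C24). PYK10 differed by 0.50 (adjusted p = 0.274), and 0 of 6 reference transcripts were called in limma, and 0 at an unadjusted p under 0.05.

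Some transcripts lay beyond both parents. Above both stood AT4G27280 (adjusted p = 1.31e-05), AT3G22240 (adjusted p = 1.89e-05), AT5G19120 and AT2G20670 (adjusted p = 3.43e-05 each), ORA47 (adjusted p = 7.05e-05), AT3G15450 (adjusted p = 8.20e-05), AT3G07350 (adjusted p = 0.000248) and AT3G46600 (adjusted p = 0.000365). AT3G46600, a GRAS-family transcription factor gene, stood at 798 ± 58.3 in F1, 229 ± 14.4 in Col and 386 ± 18.19 in C24, and AT3G15450 at 4339 ± 610, 1286 ± 295 and 1472 ± 240. Below both stood 7 named genes, petG, psbB, psbN, accD, ndhE, atpF and cemA, which encode parts of the cytochrome b6f complex, photosystem II, acetyl-CoA carboxylase, the NADH dehydrogenase-like complex and ATP synthase, and an envelope protein. All 7 are chloroplast-encoded, as are 69 of the 7354 named probe sets tested, a property looked up after the 7 were seen; of the 26 named above both parents 0 are.

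petG stood at 176 ± 37.6 in F1, 610 ± 92.5 in Col and 1426 ± 106 in C24 (adjusted p = 9.19e-05). psbB followed with 1239 ± 166 against 2289 ± 85.8 and 2097 ± 93.6 (adjusted p = 0.0135), and the other 5 each had an adjusted p of 0.0147, ndhE with 1174 ± 388 against 2842 ± 211 and 3182 ± 524 among them. In all 52 probe sets lay above and 9 below both parents. Without an intensity trend the counts were 33 and 1; the count below was 1 without C24 replicate 1, 3 without F1 replicate 3, 4 without Col replicate 2, and 5 without Col replicate 3 or C24 replicate 3. Each of the 6 other than petG lost its call without C24 replicate 1 (adjusted p = 0.0503 to 0.0855) and without an intensity trend (0.358 to 0.376). Without F1 replicate 3 psbB, psbN, accD, atpF and cemA lost it (0.0699 to 0.116), without Col replicate 2 accD, ndhE and cemA (0.0553 to 0.152), without Col replicate 3 psbN and ndhE (0.0842 and 0.117), without C24 replicate 3 atpF and cemA (0.0884 each), without F1 replicate 2 atpF (0.0680) and without Col replicate 1 psbN (0.0546).

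**Figure D2:**
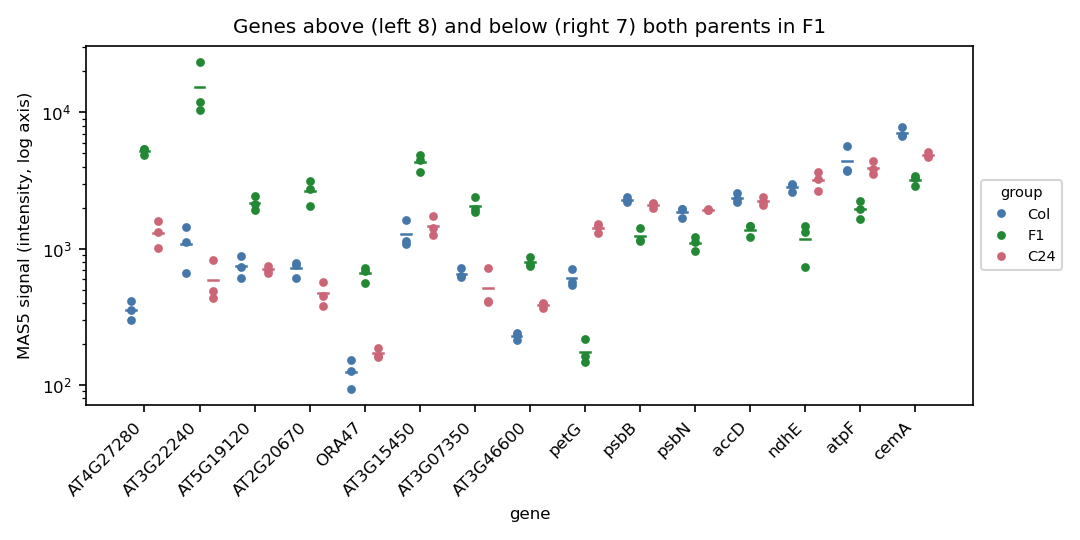
Signals of the 8 genes above both parents (left) and the 7 below both (right), on a log axis of MAS5 signal. Each point is 1 array, the dash is the mean of 3 arrays, and colours mark Col (blue), F1 (green) and C24 (red). In petG the F1 mean of 176 lies under the Col mean of 610 and the C24 mean of 1426.

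Chloroplast-encoded genes, 1 of the added lists, were tested as a group. Against the mid-parent 27 of 69 fell and 2 rose, psbK (0.45) and psbI (0.43), with 39 and 6 when adjusted over the list alone. The mid-parent is the additive level only where both parents contribute alike, which was not shown for chloroplast-encoded or mitochondrion-encoded genes. On the log2 scale, with 0 at Col and 1 at C24, psbK stood at 1.05 and psbI at 1.17, close to C24. A call here is therefore not by itself a change particular to the hybrid. The list's median against the mid-parent was -0.28 on the linear scale and -0.27 on the mean of logs that the test used (adjusted p = 1.55e-13, and adjusted p = 0.0823 with an estimated correlation). Against Col 35 were lower and 6 higher in F1 (median -0.34, adjusted p = 2.14e-12, and adjusted p = 0.101 with an estimated correlation), and against C24 19 were lower and 1 higher (median -0.15, adjusted p = 0.000659, and adjusted p = 0.243 with an estimated correlation). Between the parents 21 were lower and 8 higher in C24 (median -0.17, adjusted p = 0.0251, and adjusted p = 0.361 with an estimated correlation); rpoB, for a subunit of the chloroplast RNA polymerase, was higher (93.2 ± 25.3 in Col, 913 ± 33.4 in C24) and ndhK lower (9039 ± 562 and 4468 ± 647).

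The parental call of this list was lost with quantile normalization (adjusted p = 0.341) and without Col replicate 2 (adjusted p = 0.0603), Col replicate 3 (adjusted p = 0.0611) or C24 replicate 3 (adjusted p = 0.0553). Beside these genes, the array's GAPDH control had a 3'/5' signal ratio of 5.24 ± 0.44 in F1, 4.16 ± 0.43 in Col and 4.46 ± 0.18 in C24, an order that did not pass after adjustment over 38 control ratios (exact permutation test, adjusted p = 0.181). Its unadjusted p of 0.0119 is the smallest that test can give, so a single ratio could not pass that adjustment alone.

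**Figure D3:**
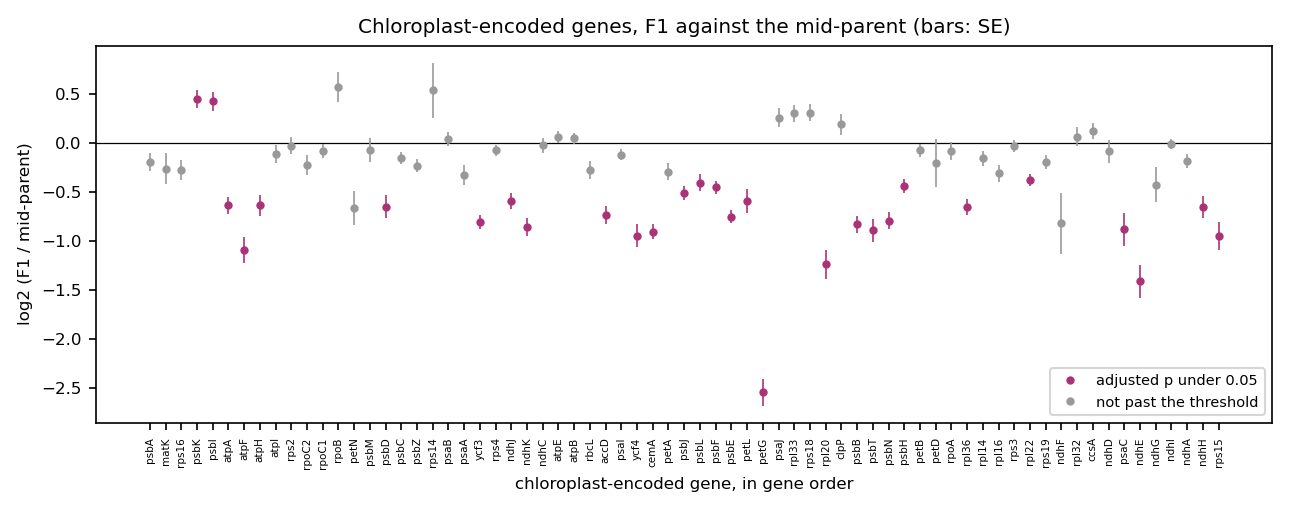
Log2 difference of F1 from the mid-parent for the 69 chloroplast-encoded genes tested, in gene order. Each point is 1 gene, bars are the SE, and colour marks an adjusted p under 0.05 (purple) or not (grey). The median is -0.28, and petG lies lowest at -2.55.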

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

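The tests of probe mismatch, of control ratios, and of an equal chloroplast loss were chosen only after the results were seen. The chloroplast list was added once the annotation had been seen, so its rerun under other scalings was not among the alternatives planned at the start, while the tests of handling, of scaling for levels above both parents and of other splits were fixed before.

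Signals in the array's own controls, outside the main measurement, stood above the level of the parents in all 3 F1 arrays for 2 of 38 ratios. The GAPDH 3'/5' ratio was 5.24 in F1 (4.16 in Col, 4.46 in C24), and the 3'/middle ratio of the dap control, a Bacillus transcript, was 2.14 in F1 (1.63 in Col, 1.67 in C24). In the other set of GAPDH probes (r2-At-GAPDH) the 3'/5' ratio was 1.77 in F1, 1.42 in Col and 1.52 in C24 (exact p = 0.0357), not above the parents in all 3 F1 arrays. The 3'/5' ratio of 1 set of thr probes (r2-Bs-thr) lay below both parents in all 3 F1 arrays (3.47 against 7.78 in Col and 8.95 in C24), but that of the other set (ThrX) did not (50.2 against 46.8 and 74.9, exact p = 0.940). The dap ratio is likewise from 1 set of probes (r2-Bs-dap); in the other (DapX) it was 2.60 in F1, 2.19 in Col and 2.29 in C24 (exact p = 0.0595). In the exact permutation test over 84 splits GAPDH and dap had p = 0.0119, the smallest it can give, thr had p = 0.0238, and the smallest adjusted p was 0.181. The 3' probe set of the actin control stood at 8302 ± 586 in Col, 1672 ± 122 in C24 and 5875 ± 470 in F1 (SD, n = 3), while its 5' probe set stood at 411, 391 and 525. Groups of 3 arrays were not tested for single outlying arrays.

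Of 69 chloroplast-encoded genes 27 were lower and 2 higher in F1 than the mid-parent, and the list passed in camera at the preset correlation but not with an estimated one (adjusted p = 0.0823). The choice among the scalings tried is argued against. On the mean of logs the list's median difference nearest to 0 under the other scalings was -0.25, against -0.27 without rescaling. The list still passed at the preset correlation (with an estimated correlation, adjusted p = 0.0713 after median centring and 0.0636 after quantile normalization). Those scalings rest on the same signals and moved the array medians by -0.039 to 0.033 (log2). The 3' probe sets of the Bacillus controls differed in F1 from the parents by -0.33 (r2-Bs-thr) to 0.0012 (r2-Bs-phe), TrpnX (2.17) aside. A shift of that size common to the F1 arrays was therefore not tested. An equal loss of all such transcripts from the mid-parent level in the F1 preparations is argued against too, because 29.0% of the 69 genes lay within 2 SE of the list's median, with genes from -2.55 to 0.58. That share cannot test an equal loss from the C24 level, because genes that differ between the parents would then scatter about the mid-parent as well. cRNA that reached less far from the 3' end in F1 stays open. The smallest adjusted p of the control ratios was 0.181, in an exact permutation test that 1 ratio alone could not pass. The median log2 difference of the plant and Bacillus ratios was 0.24 higher in F1, which does not settle it. That median includes the actin ratios (0.28 to 0.75), where F1 lay between the parents. It also includes the TrpnX ratios (2.53 and 1.89), which rest on mean signals of 0.89 to 29.4. A difference of the hybrid itself also stays open, as do unknown harvest times.

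Transcripts above both parents in F1 numbered 52. The choice among the scalings tried is argued against, because the smallest count under the other scalings was 53. Handling that varied from sample to sample may contribute: the members' deviations from their group means correlated at a mean of 0.0916 across arrays, the 100th percentile of 1000 random sets matched on signal (-0.018 to 0.0836). Genes that are regulated together would give the same value, so the 2 cannot be separated by it. Handling or harvest time that differed between F1 and the parents as groups leaves no trace in deviations from group means. It stays open, as does a difference of the hybrid itself.

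Parental differences of at least 2-fold may in part come from array probes, designed on another sequence, that bind C24 transcripts less well. A mismatch lowers the C24 signal, so the direction of the 569 probe sets higher in C24 argues against it there; they were 1.12 times as many as the 507 higher in Col. For those higher in Col it stays open: an F1 that carries both alleles would stand at 0.5 with or without a mismatch, and the median position was 0.486. ECS1 among them goes against a mismatch alone, which would put F1 midway, since F1 stood at 20823 ± 1556 and Col at 21099 ± 1322. A difference between the accessions in transcript level stays open as well.

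Other splits of the arrays into groups of the same sizes were run for each count. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05: C24 against Col gave 4220 probe sets in the real split, reached by 1 of the 10, and at most 0 in another, F1 against Col 1563 and 0, F1 against C24 1951 and 0. In the same splits 2 gene lists passed in the real one and at most 2 in another, with 3 of the 10 as large, again too few splits. Among 100 splits of the 9 arrays, 4 gave as many probe sets off the mid-parent (real value 450, highest other 3553), 2 as many above both parents (52, highest other 279) and 4 as many below both (9, highest other 462). These ranks do not exclude chance, because a split that mixes the groups puts the parental differences into the spread and so lowers its own count. Nor was chance excluded for the gene lists against the mid-parent (1 list, reached by 34 of 100, highest other 2). The highest other counts point to the structure of the samples: 3553 arose with the 3 Col arrays in the place of F1, and so did 1774 and 1699.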

How the results depend on the processing

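The added gene lists, among the choices here, were set after seeing which genes the annotation names. Of 1410 comparisons of the 83 results for named genes with an alternative, 1355 kept their direction and side of the threshold and 55, in 11 results, no longer passed; 0 reversed. Counts were 4220 for C24 against Col, 1563 for F1 against Col, 1951 for F1 against C24, 450 for the mid-parent, 52 above and 9 below both parents; over C24 against Col and the mid-parent alone, where lists were rerun in full, 3 lists fixed beforehand and 3 added lists passed. Over every comparison 81 results for named genes passed. At least 2-fold, the first 4 counts were 1076, 331, 450 and 103; at the 0.01 threshold 2692, 767, 1063 and 217. With each parental contrast passing by its own adjusted p, 117 lay above and 52 below both parents. Without an intensity trend, 264 differed from the mid-parent, 33 lay above and 1 below. The position of 0.432 was 0.381 at 4-fold, 0.361 higher in C24 and 0.486 higher in Col.

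In those 2 comparisons the added lists passing were 6 with median centring, 5 with no filter, 7 without _s_at and _x_at probe sets and 0 with an estimated correlation; the lists fixed beforehand were 5 with no filter, 1 with the 60th-percentile filter and 0 with an estimated correlation. With the 60th-percentile filter 45 named genes passed, as fewer were tested. Apart from thresholds, filters and selections, whose construction gives the cause, the cause was not tested. Scaling moved the median of all genes by at most 0.039 (log2). Setting signals below 1 to 1 changed nothing. Low signals limit the folds of genes near the filter.

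With each array left out in turn, the counts ran from 3348 to 4348 for C24 against Col, 1021 (without Col replicate 2) to 1521 for F1 against Col, 1362 to 1964 for F1 against C24, 284 (without F1 replicate 3) to 422 for the mid-parent, 35 to 53 above and 1 (without C24 replicate 1) to 10 below both parents; the position from 0.407 to 0.445, in those 2 comparisons lists fixed beforehand from 2 to 4 and added lists from 1 (without Col replicate 3) to 6 (without F1 replicate 1), and named genes from 65 to 80.

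Replicate numbers were not taken to pair the samples, since 4 of 9 same-numbered pairs, not all, had deviations correlated over 0.1 (-0.0015 to 0.117). As a hint of shared handling, 16 of 18 choices were best with their own number, and same-numbered pairs had a mean of 0.083. The mean of -0.042 for other pairs adds nothing to this, because deviations cancel within each group. With the replicate number as a block the counts were 4471, 1844, 2255, 595, 59 and 13, the position 0.432, the lists of those 2 comparisons 3 and 2, and the named genes 81; the mitochondrial list's mid-parent call was lost (adjusted p = 0.0879).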

Other observations

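The test of chloroplast inheritance was chosen only after the result was seen.

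The other added lists missed the threshold of camera between the parents, and the members called in each stand beside 30.9% called among all probe sets. Of 10 CYP71B cytochromes P450 4 rose in C24, CYP71B24 from 211 ± 28.6 to 885 ± 149 and CYP71B6 from 842 ± 5.93 to 1840 ± 29.0 (SD, n = 3; list adjusted p = 0.0507). Of 15 genes of endoplasmic reticulum quality control 5 rose, among them BZIP60, a regulator of the unfolded protein response (0.61), and ATERDJ3B (0.57), with adjusted p = 0.0507 for the list. Of 9 mitochondrion-encoded genes 4 rose, ccb382 by 1.23 and cox1 by 0.94 (list adjusted p = 0.0507), and of 23 factors of chloroplast RNA editing and photosystem assembly 9 fell and 2 rose, SECE1 by -1.02 and LPA66 by -0.65 (list adjusted p = 0.0507). After median centring the P450, mitochondrial and RNA editing lists each had an adjusted p of 0.0452, and with an estimated correlation adjusted p = 0.207, 0.207 and 0.337. Of 22 UDP-glycosyltransferases 8 fell and 4 rose (list adjusted p = 0.189): UGT78D1, a flavonol rhamnosyltransferase, stood at 1591 ± 134 in Col and 99.4 ± 21.6 in C24 (-4.02), and UGT72E1 rose by 1.92. Of 7 SWEET sugar transporters 4 fell (SWEET2 -1.08), of 6 tau-class glutathione transferases 2 rose (GSTU26 2.12, GSTU27 1.41), and of 4 calmodulin-like genes 2 rose (CML41 3.12); each list had an adjusted p of 0.189. Of 6 tetraspanins TET8 rose (1.06; list adjusted p = 0.355), of 6 expansins 2 rose and 2 fell (list adjusted p = 0.799), of 5 plant U-box ligases 2 rose and 1 fell (PUB19 2.55; list adjusted p = 0.861), and of 11 ESCRT and VPS genes 2 rose and 1 fell (VPS2.2 -2.22; list adjusted p = 0.945). The 2 xyloglucan endotransglucosylase genes tested did not pass.

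Several of these lists set F1 apart from C24. Of 15 genes of endoplasmic reticulum quality control 4 were lower in F1 (adjusted p = 0.0183, and adjusted p = 0.123 with an estimated correlation), as were 3 of 10 CYP71B genes (adjusted p = 0.0193, and adjusted p = 0.123 with an estimated correlation) and 3 of 9 mitochondrion-encoded genes (adjusted p = 0.00664, and adjusted p = 0.123 with an estimated correlation). Factors of chloroplast RNA editing and photosystem assembly were higher in 4 of 23 (adjusted p = 0.0290, and adjusted p = 0.339 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0961). Against the mid-parent 4 of 9 mitochondrion-encoded genes were lower, ccb382 (-1.04), orfX (-0.87), nad4 (-0.65) and cox1 (-0.65), with a list median of -0.02 on the mean of logs that the test used (adjusted p = 0.0441, and adjusted p = 0.199 with an estimated correlation) and -0.08 on the linear mid-parent. That call was lost with no filter (median 0.09, adjusted p = 0.503) and with the mean over a gene's probe sets (adjusted p = 0.0793). It was lost too with the replicate number as a block (adjusted p = 0.0879). The same held without Col replicate 1 (0.0771), Col replicate 3 (0.0731), C24 replicate 2 (0.0510) or F1 replicate 1 (0.160). With 1 array left out the median ran from -0.36 (without C24 replicate 3) to 0.06 (without F1 replicate 1). TET8 (0.81) and EXLB1 (0.62) were higher than the mid-parent. NAI2 and PYK10, both tied to endoplasmic reticulum bodies, were each far lower in C24 than in Col (-7.60 and -4.98), an observation made after their values were seen. PYK10 was also listed as a root marker, and a different share of root tissue in the samples was not tested.

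A hypothesis is that the F1 carried the chloroplasts of C24, the seed parent in the usual reading of a cross written C24 x Col, which may set the level of chloroplast-encoded transcripts that differ between the parents. Each gene's F1 position on the log2 scale, with 0 at Col and 1 at C24, had a median of 1.02 over the 8 genes higher in C24 and 1.25 over the 21 higher in Col. petL (-0.07) and petG (-1.46) among the 8, and ccsA (0.20) and ndhI (0.52) among the 21, go against it, while rpl20 (2.88), ycf4 (2.29) and cemA (2.11) lay far beyond C24. A general fall of these transcripts in F1 would raise the second value, so the first bears more on the hypothesis, and a different level set by nuclear genes of C24 acting over those of Col was not tested. Among the 8 genes behind the first, psbK and psbI are neighbours in gene order. So are petL, petG, psaJ, rpl33 and rps18, and the 8 may therefore not be independent. The mitochondrion-encoded ccb382 and cox1 were higher in C24 but lay on the Col side of the mid-parent in F1. If the seed parent also gave the mitochondria, they go against C24 as that parent. Positions between the parents were not computed for mitochondrion-encoded genes.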
